A study of Bacillus cereus with 16 samples.

How the data were processed

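The 16 arrays were 2-colour Agilent arrays hybridised with total RNA of Bacillus cereus ATCC 14579, grown in a rich broth at 30 °C and 200 rpm to an optical density of 0.5, per the labels' protocols. Exposure times of 0, 1, 2 and 5 min per sector, the treatment of each extract and the dye of each channel were taken from the labels. Scanner intensity values of each spot and its local background, which the authors deposited per array, were used as the starting point. The spots had been quantified with Agilent Feature Extraction, whose modules give version 9.5.1.1 per the file headers, while the submitters' processing notes name version 8.1.1.1. The deposited log10 ratios of Cy5 over Cy3 of each spot, made by Feature Extraction after its own background subtraction and dye normalization per the file headers, served as an alternative. The deposited value table of the series held these log10 ratios, with the sign turned on arrays that carried the plasma extract in Cy3, so that its direction is plasma over control; its values differed from the scanner files by at most 5e-06 in log10 units, and its column medians lay between -0.0065 and 0. No scale, centring or direction of that table stayed open.

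Of the 11240 features on each array, 536 were controls. Background was corrected with normexp (offset 50) on mean signals and median local backgrounds, and log2 ratios were normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots were then left out, spots flagged as non-uniform or population outliers (0.0093% to 2.08% of spots per array) were set to missing, and the 2 spots of a locus were averaged; at 98 of 5352 loci both spots carried the same sequence. Loess centres each array, so all changes are relative to the array's overall signal. Depth on an array is the signal over background, given with the results.

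Each log2 ratio was modelled with limma (lmFit and eBayes) over 14 arrays with a coefficient for each of the 7 comparisons, turned to plasma over control by the dye orientation, and 1 common dye term, which leaves 6 residual degrees of freedom per locus. P-values were adjusted over all loci by the Benjamini-Hochberg method and called at 0.05. The dye term itself passed for 972 loci, a number that may include differences between replicate extracts. Differences between exposures, and nitrogen flow against untreated, were contrasts of these coefficients. The untreated extract of each of replicates c and d was hybridised on 3 arrays, so correlations between exposures against untreated cells are given only between arrays without a common extract. Replicate letters are those of the array titles. The nitrogen flow arrays titled a held the plasma extract lettered b and the nitrogen flow extract lettered a at 1, 2 and 5 min, those titled b the reverse, and at 0 min the titles followed the plasma extract instead. The b_2 arrays held both extracts lettered b, so they share the nitrogen flow extract with array b and the plasma extract with array a. They entered the fits only as an alternative, which puts that plasma extract into both replicates. Their channels were also part of the principal components and of the mean channel correlations with 2 min extracts. The fit was tested on simulated data for 5346 loci with 200 changed: for plasma against nitrogen flow at 1 min 95% of changes of log2 1 and 99% of changes of log2 2 were recovered with 10 false calls among 204, and for plasma against untreated at 5 min 98% and 100% with 11 among 209. The noise was independent, drawn from the fitted variances, and no other comparison carried an effect. These rates therefore check the fit under its own assumptions and are not error rates of the real data.

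Loci to be named were chosen by a rule written before the data were examined, as those with the largest absolute log2 ratio among loci with an adjusted p under 0.05 that moved the same way on both arrays. Its condition on annotated symbols or products, its list of genes to be reported in any case and the 22 gene lists written with it could not be applied, because the files do not pair probe names with genes and no reference was used here; of each comparison 2 loci that rose and 2 that fell are therefore given. Loci named sRNA or BCp were tested as classes with camera (preset correlation 0.01), the order of locus numbers was compared with 1000 random orders, and the channels of the slide with the nitrogen flow comparisons were fitted separately, after loess and Aquantile normalization; these 3 analyses were added after the data were seen. Principal components were taken of channel intensities after loess and Aquantile, with the mean of each dye removed.

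The alternatives written beforehand were the Feature Extraction log ratio, no background correction, median centring, a filter on dim loci (well above background in either channel on at least 50% of arrays, which left out 204 loci), outlier spots kept, b_2 arrays averaged with replicate b, no dye term, a dye term for each of the 2 slides, the replicate letter as a random block on log2(Cy5/Cy3) (duplicateCorrelation), the arrays of 1 slide alone, the median over probes (for 2 spots equal to the mean, so that it tests nothing), the deposited value table (the Feature Extraction log ratio again, so not a separate test), and leaving out each array in turn. After the data were seen, these were added: the test of 2 min minus 1 min, the 1 and 2 min arrays of replicate c exchanged or both left out, the same block on plasma-over-control ratios, and that block with letters c and d exchanged at 2 min. The comparisons with nitrogen flow and those with untreated cells lay on different slides, so slide enters the difference between them; nitrogen flow against its own 0 min extracts was therefore also fitted within 1 slide. The letter of the plasma extract coincided with the dye orientation in all 7 comparisons, so letter and dye cannot be told apart.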

Results

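Transcript levels of Bacillus cereus ATCC 14579 were measured on 16 Agilent arrays, each carrying RNA of 2 extracts labelled with Cy3 and Cy5. Exponentially growing cells had been collected on filters and exposed on agar plates of 6 sectors to a low-temperature nitrogen gas plasma, or to the nitrogen flow alone, for 0, 1, 2 or 5 min per sector. Plasma-treated and untreated extracts shared an array at 1, 2 and 5 min, with replicates c and d at each exposure. Plasma and nitrogen flow extracts shared an array at 0, 1, 2 and 5 min, with replicates a and b at each. Replicate letters are those of the array titles; each array of replicates a and b set a plasma-arm extract lettered a against a nitrogen-arm extract lettered b, or the reverse. Both arrays of a comparison carried the dyes in opposite orientation. A further array, termed b_2 in the labels, existed at 2 and at 5 min and was kept out of the main tests. Probes covered 5352 loci, of which 5249 had a numbered BC name, 21 a BCp name and 82 an sRNA name, each with 2 spots. At 98 loci, 52 of them named sRNA, both spots carried the same probe sequence. Median spot intensity over a local background of 56 to 67 units ranged from 356.6 to 898.2 units in Cy3 and from 792.6 to 1885.5 units in Cy5. The share of spots well above background lay between 69.5% and 93.5% in Cy3 and between 63.6% and 94.6% in Cy5, with the lowest share in both channels on the 2 min nitrogen flow array of replicate a. The number of arrays, 2 per comparison, limits the precision. Since the labels do not say that replicates came from separate cultures, p-values measure at most the spread between these samples. Part of that spread may be missing from them. The dye term, which coincides with the extract letter, can take up differences between replicate extracts that recur across comparisons. The arrays against untreated cells also share the untreated extract of each replicate, so they are not independent. The files do not pair the probe names with gene names or products, so loci are given by their array names, with the log2 ratio, its standard error and the adjusted p of limma.

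The comparison at 0 min set extracts of the plasma arm against extracts of the nitrogen arm, both untreated, and so gave the background of the measurement. No locus passed an adjusted p of 0.05 in limma, and 162 of 5352 did at an unadjusted p of 0.05. The SD of log2 ratios over all loci was 0.18 and 0.19 on these arrays. BC3BC1083, the locus with the highest ratio after 1 min of plasma against untreated cells, differed at 0 min by -0.03 ± 0.13 (SE, n = 2; limma adjusted p = 0.998). The 21 loci named BCp, none of which passed, had a median log2 ratio of 0.10 at 0 min (camera adjusted p = 0.00051 over 14 tests with the preset correlation, adjusted p = 0.94 with an estimated correlation). Those named sRNA had a median of 0.02 (camera adjusted p = 0.24).

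**Figure D1:**
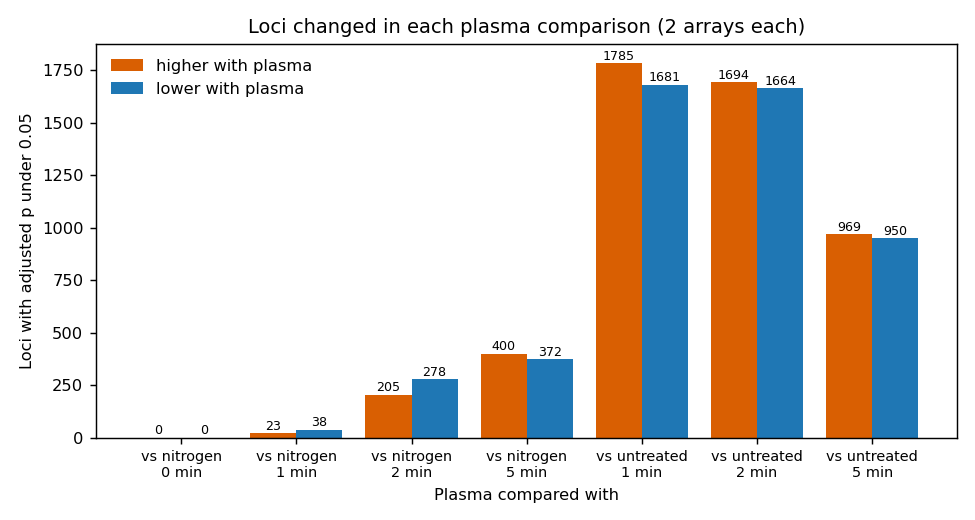
Number of loci with an adjusted p under 0.05 in limma (y axis) in each plasma comparison (x axis), split into loci higher (orange) and lower (blue) with plasma. No locus passed at 0 min, and the counts against untreated cells fell from 1785 higher and 1681 lower at 1 min to 969 and 950 at 5 min.

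Against untreated cells, 1 min of plasma was accompanied by higher signal of 1785 loci and lower signal of 1681 loci, together 64.8% of those tested. The balance of directions depended on the scaling, with 1489 higher and 1874 lower with the Feature Extraction log ratio and 1443 and 1521 with median centring. The rises were the larger changes. At least 4-fold differences were reached by 258 loci that rose and 70 that fell, and at least 16-fold differences by 94 and 2. BC3BC1083 (probe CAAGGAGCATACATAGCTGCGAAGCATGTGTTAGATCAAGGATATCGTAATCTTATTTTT) rose 209.5-fold, a log2 ratio of 7.71 ± 0.13 with 7.48 and 7.94 on the arrays of replicates c and d (limma adjusted p = 2e-09). BC3BC1034 (probe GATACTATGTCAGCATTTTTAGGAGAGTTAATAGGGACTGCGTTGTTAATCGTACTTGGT) rose by 7.08 ± 0.36 (limma adjusted p = 4.7e-07). The deepest decreases were those of BC3BC4208 (probe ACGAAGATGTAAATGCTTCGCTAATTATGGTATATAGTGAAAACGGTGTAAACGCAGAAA), at -4.18 ± 0.10, and BC3BC1954 (probe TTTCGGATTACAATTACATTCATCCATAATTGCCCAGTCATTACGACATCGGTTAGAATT), at -4.06 ± 0.33 (limma adjusted p = 1.2e-08 and 6.5e-06). Both probes of each of these loci moved alike, and across the 5249 numbered loci, 46 of them with 1 sequence spotted on both places, the probes of a locus correlated with r = 0.95; they had opposite signs at 71 of 3401 loci that passed. Loci named sRNA were divided evenly, with 27 that rose, 27 that fell and 28 that did not pass, while 10 of 21 loci named BCp rose and 1 fell (camera adjusted p = 0.72 and 0.11).

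After 2 min of plasma, 1694 loci were higher and 1664 lower than in untreated cells, against 1358 and 1846 with the Feature Extraction log ratio and 1445 and 1514 with median centring. BC3BC1083 rose by 7.71 ± 0.13 and BC3BC1034 by 7.56 ± 0.36, whereas BC3BC4208 fell by 3.99 ± 0.10 and BC3BC3669 (probe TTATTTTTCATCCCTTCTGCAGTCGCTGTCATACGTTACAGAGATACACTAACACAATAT) fell by 3.94 ± 0.39. Their limma adjusted p-values were 2.1e-09, 3.1e-07, 1.5e-08 and 2.6e-05. Of the loci named BCp 12 rose and 1 fell, and of those named sRNA 26 rose and 25 fell (camera adjusted p = 0.022 and 0.997, adjusted p = 0.94 and 0.999 with an estimated correlation). A test of the difference between 2 and 1 min, added after the data were seen, called 0 of 5352 loci in limma, with 23 at an unadjusted p of 0.05. The arrays of the comparison stood in a crossed relation. Across loci, the 1 min array of replicate c correlated more with the 2 min array of replicate d (r = 0.96) than with the 1 min array of replicate d (r = 0.92). With the 1 and 2 min arrays of replicate c exchanged, the test called 331 loci, and the counts against untreated cells became 3518 at 1 min and 3800 at 2 min. The exchange was chosen because of this better agreement, which itself favours more calls. These counts are therefore no evidence for an exchange.

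By 5 min the difference from untreated cells was smaller, with 969 loci higher and 950 lower, against 843 and 854 with the Feature Extraction log ratio and 945 and 1037 with median centring. At least 4-fold differences were reached by 10 loci that rose and 1 that fell. BC3BC4870 (probe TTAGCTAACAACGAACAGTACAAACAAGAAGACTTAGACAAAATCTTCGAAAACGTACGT) was 21.1-fold higher, at 4.40 ± 0.41 (limma adjusted p = 0.00023), after 6.79 ± 0.41 at 1 min. BC3BC5438 (probe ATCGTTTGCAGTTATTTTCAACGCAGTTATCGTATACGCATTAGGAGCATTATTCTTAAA) rose by 3.23 ± 1.06 (limma adjusted p = 0.041), a call that ended under 6 of 14 distinct alternatives, among them either array left out. BC3BC3669 fell by 2.01 ± 0.39 and BC3BC5133 (probe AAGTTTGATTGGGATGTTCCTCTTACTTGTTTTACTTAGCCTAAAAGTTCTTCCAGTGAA) fell by 1.97 ± 0.17 (limma adjusted p = 0.0048 and 0.00018); without replicate d the first of these fell by 1.59 (limma adjusted p = 0.13). BC3BC1083 was 0.88 ± 0.13 above untreated at this exposure, and BC3BC4208 differed by -0.22 ± 0.10 (limma adjusted p = 0.0014 and 0.12). Of 82 loci named sRNA 37 rose and 13 fell, and of 21 loci named BCp 2 rose and 12 fell (camera adjusted p = 0.0042 and 0.0031 over 14 tests with the preset correlation, both 0.94 as adjusted p with an estimated correlation). The count of 1919 loci became 586 without replicate c, 559 without replicate d and 879 when only the arrays of the same slide were fitted.

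The change between 1 and 5 min was tested directly. The effect against untreated cells was higher at 5 min than at 1 min for 1175 loci and lower for 1328, 46.8% of all. With the Feature Extraction log ratio the balance turned, with 1333 higher and 1071 lower. BC3BC1034 fell by 6.86 ± 0.51 and BC3BC1083 fell by 6.83 ± 0.19, while BC3BC1954 went up by 4.64 ± 0.46 and BC3BC4208 by 3.96 ± 0.14 (limma adjusted p = 1.2e-05, 1.5e-07, 5.9e-05 and 3.2e-07). Without the 5 min array of replicate c the count was 1664.

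**Figure D2:**
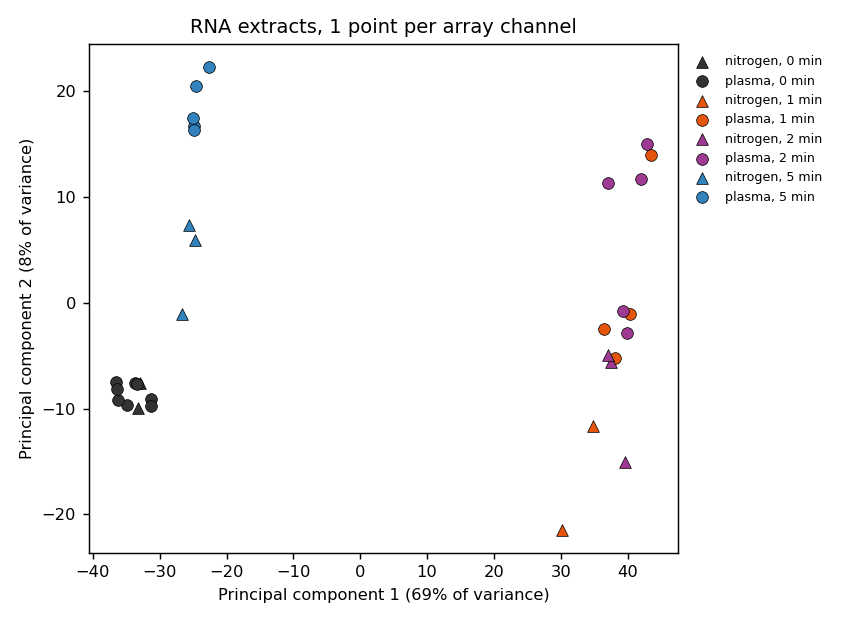
Position of each array channel on the first principal components of normalized log2 intensity over all loci (axes in component units, with the percent of variance), by exposure (colour) and treatment (circle, plasma arm; triangle, nitrogen arm). All 1 and 2 min extracts lie between 30.2 and 43.6 on the first component and all 0 and 5 min extracts between -36.6 and -22.7.

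The arrays of plasma against nitrogen flow separated the plasma from the gas stream that carried it. After 1 min, 23 loci were higher and 38 lower with plasma. BC3BC0194 (probe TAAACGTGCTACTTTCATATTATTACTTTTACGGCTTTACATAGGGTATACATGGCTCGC) rose 8.68-fold, at 3.12 ± 0.38, and BC3BC3643 (probe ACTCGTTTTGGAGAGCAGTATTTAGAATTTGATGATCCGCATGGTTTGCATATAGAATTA) rose 6.91-fold, at 2.79 ± 0.12 (limma adjusted p = 0.015 and 1.1e-05). BC3BC3648 (probe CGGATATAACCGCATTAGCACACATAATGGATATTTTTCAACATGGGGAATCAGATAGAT) fell by 2.06 ± 0.32 and BC3BC4452 (probe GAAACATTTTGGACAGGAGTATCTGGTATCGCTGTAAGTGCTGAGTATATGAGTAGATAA) fell by 1.72 ± 0.25 (limma adjusted p = 0.023 and 0.02). None of the loci named sRNA rose and 1 fell, and no locus named BCp passed (camera adjusted p = 0.19 and 0.60). Among the 4 named loci, BC3BC3643 alone passed under all 14 distinct alternatives; the calls of the other 3 ended without replicate a and without replicate b, and those of BC3BC3648 and BC3BC4452 also without the dye term. Over all alternatives the log2 ratio ranged from 2.95 to 3.41 for BC3BC0194, -2.48 to -1.64 for BC3BC3648 and -1.83 to -1.60 for BC3BC4452. The count of 61 loci became 4 without replicate a, 26 without replicate b, 24 without the dye term and 136 with the arrays of the same slide alone. Median centring moved the share of higher loci among the calls from 37.7% to 48.8%, and leaving out the dye term to 70.8%.

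After 2 min, 205 loci were higher and 278 lower with plasma than with nitrogen flow. BC3BC1024 (probe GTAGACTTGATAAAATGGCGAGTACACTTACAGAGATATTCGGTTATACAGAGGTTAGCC) and BC3BC1308 (probe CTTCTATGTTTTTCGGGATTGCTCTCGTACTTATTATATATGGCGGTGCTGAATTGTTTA) rose 10.6-fold each, at 3.41 ± 0.34 and 3.40 ± 0.44, and BC3BC3648 and BC3BC4452 fell by 2.69 ± 0.32 and 2.48 ± 0.25 (limma adjusted p = 0.0021, 0.0054, 0.0041 and 0.0022). BC3BC3643 rose by 2.54 ± 0.12, on both arrays. None of the loci named sRNA rose and 7 of 82 fell (camera adjusted p = 0.0089, adjusted p = 0.94 with an estimated correlation), and of those named BCp 1 rose and 1 fell (camera adjusted p = 0.29). Without replicate a the calls of BC3BC1024, BC3BC1308, BC3BC3648 and BC3BC4452 ended, and without replicate b those of BC3BC1308 and BC3BC3648. Over all alternatives the log2 ratios of these loci ranged from 3.28 to 3.64, 3.22 to 4.10, -2.86 to -2.67 and -2.89 to -2.16. The count of 483 loci became 9 without replicate a, 45 without replicate b, 848 without background correction, 822 with the Feature Extraction log ratio and 174 without the dye term; averaging the b_2 array, whose plasma extract is also on the array of replicate a, with replicate b gave 790, and a dye term for each slide gave 197.

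After 5 min, 400 loci were higher and 372 lower with plasma than with nitrogen flow. With median centring the count was 522, below the 595 at 2 min. The largest rises were those of sRNABC3BC063 (probe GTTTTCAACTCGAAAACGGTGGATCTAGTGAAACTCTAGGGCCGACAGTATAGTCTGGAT), at 2.18 ± 0.44, and sRNABC3BC001 (probe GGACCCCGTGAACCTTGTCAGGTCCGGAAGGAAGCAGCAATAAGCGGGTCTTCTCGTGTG), at 1.79 ± 0.21 (limma adjusted p = 0.013 and 0.0016), each measured with a single probe sequence spotted at both places. BC3BC5020 (probe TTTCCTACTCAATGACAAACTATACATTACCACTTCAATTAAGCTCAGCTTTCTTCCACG) fell by 2.79 ± 0.40 and BC3BC4452 fell by 2.71 ± 0.25 (limma adjusted p = 0.0034 and 0.00072). Of the loci named sRNA 19 rose and 3 fell, and of those named BCp 2 rose and 7 fell (camera adjusted p = 0.00035 and 0.011, both 0.94 as adjusted p with an estimated correlation). Without replicate b the calls of sRNABC3BC063, at 1.45, and BC3BC5020, at -2.11, ended (limma adjusted p = 0.20 and 0.071). The count of 772 loci became 148 without replicate a, 248 without replicate b, 1301 without background correction and 411 without the dye term, and median centring moved the share of higher loci from 51.8% to 34.5%. Between 1 and 5 min the effect against nitrogen flow differed for 35 loci, 27 of them higher at 5 min; the count ranged from 7 to 193 over the alternatives that kept all 14 arrays, and was 3 without either array of 1 min and 6 without the 5 min array of replicate b. The share of higher loci was 77.1%, against 45.8% with median centring, 62.9% with the Feature Extraction log ratio and 28.6% without the dye term.

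**Figure D3:**
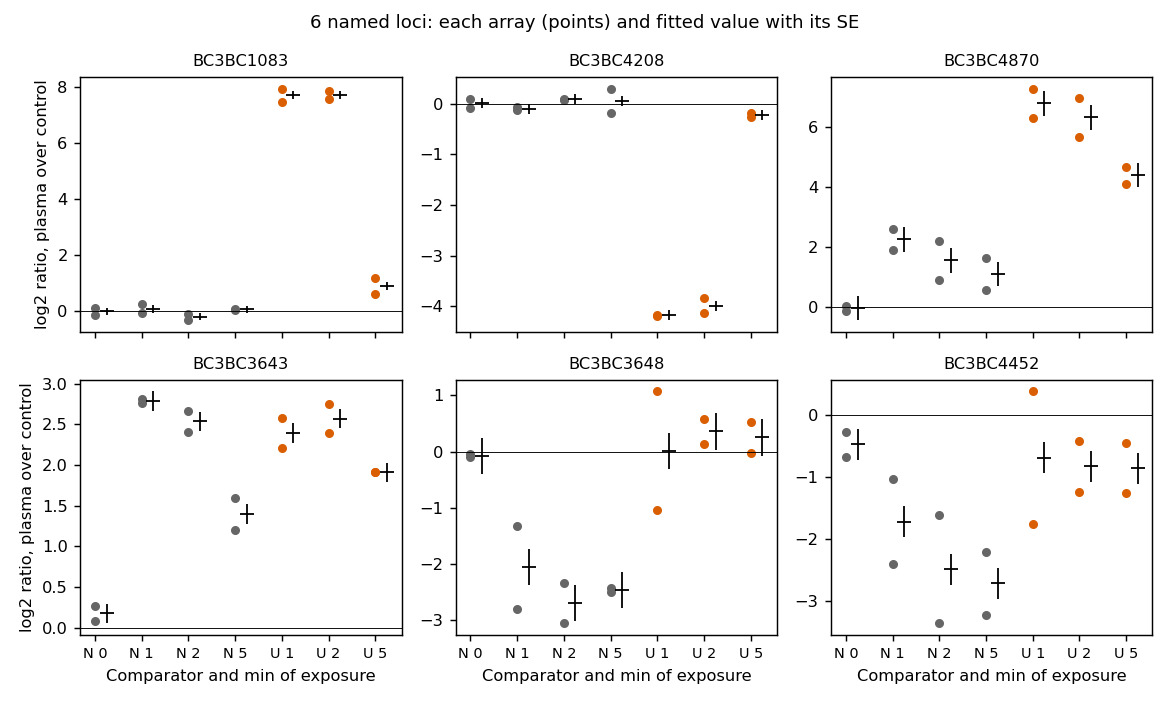
Log2 ratio of plasma over its comparator (y axis) of 6 named loci on every array (points) with the fitted value and its SE (black); the x axis gives the comparator (N, nitrogen flow, grey; U, untreated, orange) and the exposure in min. BC3BC1083 and BC3BC4208 differ from untreated cells at 1 and 2 min with ratios to nitrogen flow between -0.33 and 0.30, whereas BC3BC3643 is higher against both comparators at 1, 2 and 5 min.

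The effects of plasma against both comparators came from separate extracts and could be set against each other. Across loci, which are not independent replicates, they correlated with r = 0.33 at 1 min, 0.20 at 2 min and 0.63 at 5 min. BC3BC3643 was higher in all 6 comparisons, by 2.40 ± 0.12, 2.57 ± 0.12 and 1.91 ± 0.12 against untreated cells at 1, 2 and 5 min and by 2.79 ± 0.12, 2.54 ± 0.12 and 1.40 ± 0.12 against nitrogen flow. At 5 min 333 loci were higher in both comparisons, where independent lists would share 72.4, and 242 were lower in both, where 66.0 would be shared; 6 loci went opposite ways, where 138.3 would. At 2 min 132 loci were higher in both and 126 lower in both, against 64.9 and 86.4 for independent lists, and 113 went opposite ways, against 151.7. At 1 min the shared loci were 23 higher and 18 lower, against 7.67 and 11.9, and 9 went opposite ways, against 19.9. Both lists came from the same fit with a common variance per locus. They were therefore not independent, and the numbers for independent lists are only a rough guide. The correlation at 2 min became 0.051 without the array of plasma against untreated of replicate d, which leaves that of replicate c, part of the crossed relation. With the 2 min nitrogen flow arrays of replicates a and b, the array of replicate c correlated at r = 0.16 and -0.02. That of replicate d correlated with them at 0.31 and 0.17.

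**Figure D4:**
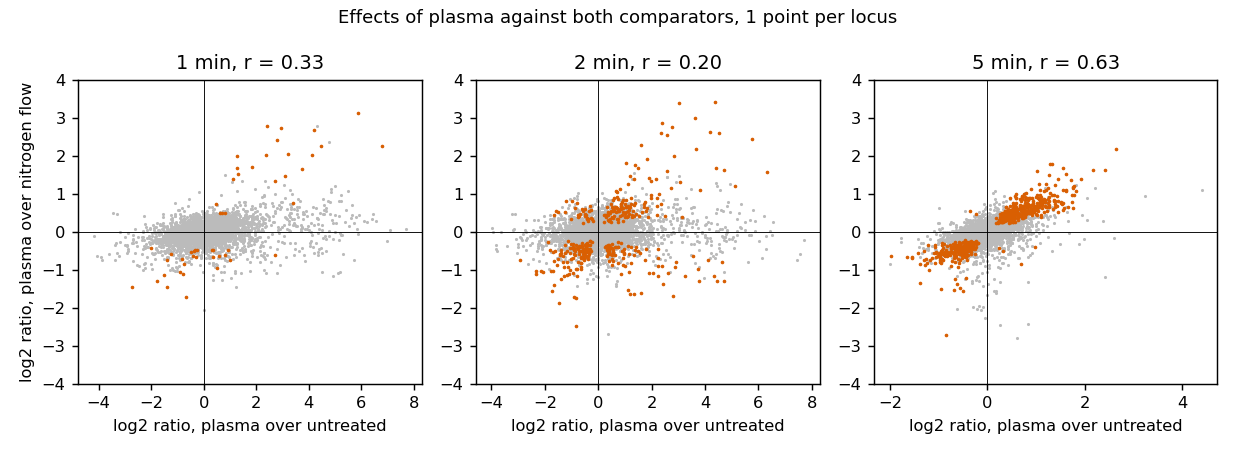
Log2 ratio of plasma over nitrogen flow (y axis) against log2 ratio of plasma over untreated (x axis) at 1, 2 and 5 min; each point is a locus, orange where both comparisons passed an adjusted p of 0.05. The orange points lie mainly in the upper right and lower left at 5 min, where r was 0.63, and in all quadrants at 2 min, where r was 0.20.

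Nitrogen flow against untreated cells was not hybridised directly and was obtained as the difference of both plasma comparisons, which lay on different slides. It gave 1295 loci higher and 1190 lower at 1 min, 1286 and 1179 at 2 min, and 61 and 52 at 5 min. With the Feature Extraction log ratio the balance turned to 1029 higher and 1308 lower at 1 min and 1051 and 1334 at 2 min. BC3BC1083 was higher with nitrogen flow by 7.65 ± 0.19 at 1 min and 7.94 ± 0.19 at 2 min and BC3BC4208 lower, at -4.08 ± 0.14 at both exposures (limma adjusted p = 4.7e-08, 4.8e-08, 3.3e-07 and 3.3e-07). BC3BC3648, lower with plasma than with nitrogen flow, was higher with nitrogen flow than in untreated cells by 2.07 ± 0.46, 3.05 ± 0.46 and 2.71 ± 0.46 at 1, 2 and 5 min (limma adjusted p = 0.0052, 0.00062 and 0.028). Its log2 ratio of plasma to untreated, which did not pass, was 0.01 ± 0.32, 0.36 ± 0.32 and 0.25 ± 0.32. At 1 min this ratio was the mean of opposite values, -1.05 on the array of replicate c and 1.07 on that of replicate d. At 5 min the count of 113 became 0 in limma without the array of plasma against untreated of replicate d (571 at an unadjusted p of 0.05) and 1 without that of replicate c, and 14 and 5 without the nitrogen flow arrays of replicates a and b; median centring gave 49, a dye term for each slide 38 and no dye term 13.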

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

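The tests that weigh both patterns below, and the look at the b_2 arrays, were chosen after the result was seen; the tests of 5 min against 1 min were planned. The effect of plasma against untreated cells differed between 5 and 1 min for 2503 loci in limma, and that against nitrogen flow for 35 loci, by a test of the difference itself in each case.

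The first pattern is that effects at 1 and 2 min were much larger than at 5 min, in the nitrogen arm as well: fitted by channel, 1115 loci differed between nitrogen flow of 1 min and its own 0 min extracts, 1410 at 2 min and 14 at 5 min. This fit called few loci at small effects: 126 for plasma at 5 min, against 1919 in the direct comparison on the other slide. The SD over loci of the nitrogen flow effects was 0.96, 1.03 and 0.45 at 1, 2 and 5 min, and that of plasma at 5 min was 0.51. The count of 14 therefore does not show that nitrogen flow had no effect at 5 min. For plasma against untreated cells, the ratio of the SD of the 1 min effects to that of the 5 min effects was at least 2.28 without loess, without background correction or with the Feature Extraction log ratio, which argues against the normalization as the cause. The untreated channel of an extract correlated with at least r = 0.93 between its arrays. Different extracts came close to this (0 min plasma-arm extract a with untreated extract c, r from 0.885 to 0.906), so this value cannot exclude a reference that differed between arrays. On the first principal component all 0 min plasma-arm channels lay between -36.6 and -31.2, and the 1 min ones between 36.5 and 43.6. A reference difference of that size is thus not seen, while a smaller one stays possible. Extracts of 1 and 2 min handled apart from those of 0 and 5 min cannot be told apart from exposure time, since nitrogen flow moved the extracts nearly as far as plasma did (ratio of SDs 0.96) and the labels give no handling batch. A response to handling and gas flow that was weaker at the longest exposure may therefore be at work, and it stays open and untested beside a handling batch.

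The second pattern is the crossed relation of the 1 and 2 min arrays of replicates c and d. The difference of 2 min minus 1 min correlated across loci with r = -0.75 between replicates c and d, and with the mean of replicates a and b, read from single channels, with r = -0.66 for replicate c and 0.70 for replicate d. Against replicate a alone the value for replicate c was -0.29, and against replicate b alone -0.65; for replicate d these were 0.37 and 0.61. With the 1 and 2 min plasma channels of replicates a and b, the 2 min extract of replicate c had mean r = 0.88 and 0.71, and its 1 min extract 0.75 and 0.79. For replicate d they were 0.78 and 0.81 at 2 min, and 0.87 and 0.70 at 1 min. The means over 2 min channels include the b_2 array, which lies on the slide of replicates c and d. With that channel the 2 min extract of replicate d correlated at 0.93. With the other 2 min channels it correlated at 0.67 and 0.81, against 0.78 with each 1 min channel. Its larger mean with 2 min thus rests on b_2. For the 1 min extract of replicate c the mean was not taken without b_2. Single values overlapped for the 1 min extract of c and the 2 min extract of d. An exchange of the 1 and 2 min extracts of replicate c would give the signs of the correlations of 2 min minus 1 min differences. It is a candidate explanation. Variation between replicates unrelated to exposure stays open, because replicates a and b did not share a 2 min minus 1 min difference either (r = -0.10). The labels were kept in all reported values.

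The b_2 arrays, left out of the main fit, had an SD of log2 ratios of 0.38 at 2 min and 0.46 at 5 min, against 0.18 and 0.19 on the arrays at 0 min. They correlated with replicate b, whose nitrogen flow extract they share, with r = 0.93 and 0.89, and with the arrays of replicate a, which hold the same plasma extracts (lettered b), with r = 0.62 and 0.69.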

How the results depend on the processing

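The test of 2 min minus 1 min, the exchange of replicate c arrays, their joint omission, the block on plasma-over-control ratios and the crossed letters were chosen after the data were seen. The counts against untreated cells at 1 and 2 min, and those of nitrogen flow against untreated at these exposures, stayed within 1.5 times their value under every alternative run. The count at 0 min stayed at 0, its floor, which says little about stability. Of 203 recomputed counts 165 stayed within 1.5 times, a count of 0 that stayed 0 included. These leave out the median over probes, equal to the mean by construction, and the value table, which repeats the Feature Extraction ratio. The cause of the other changes was not tested, except that leaving out arrays leaves fewer samples, the remaining one being assumed to vary like the other groups. Against nitrogen flow at 1 min (61) the count was 24 with no dye term and 136 with 1 slide. At 2 min (483) it was 822 with the Feature Extraction log ratio and with the deposited value table, 848 with no background correction, 790 with b_2 averaged, 174 with no dye term and 197 with a dye term for each slide. At 5 min (772) it was 1301 with no background correction and 411 with no dye term. Plasma against untreated at 5 min (1919) gave 879 with 1 slide. For 5 min minus 1 min against nitrogen flow (35) the counts were 89 with the Feature Extraction log ratio and with the value table, 193 with no background correction, 161 with b_2 averaged, 7 with no dye term, 16 with a dye term for each slide and 11 with 1 slide. Nitrogen flow against untreated at 5 min (113) gave 49 with median centring, 13 with no dye term and 38 with a dye term for each slide. The test of 2 min minus 1 min (0 loci, 23 at an unadjusted p of 0.05) gave 331 with replicate c exchanged.

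With each array left out in turn, counts ranged from 4 to 26 against nitrogen flow at 1 min, 9 to 45 at 2 min and 148 to 248 at 5 min, from 3 to 31 for its 5 min minus 1 min difference, from 559 to 586 for plasma against untreated at 5 min, from 1664 to 2017 for its 5 min minus 1 min difference and from 0 to 14 for nitrogen flow against untreated at 5 min. The correlation of both plasma effects at 2 min ranged from 0.051 to 0.33.

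By the letter of the plasma extract, deviations correlated across loci with r from 0.10 to 0.55 for letters a and b and from -0.19 to 0.46 for c and d, and after removal of the dye term from -0.55 to 0.11 and -0.78 to 0.28. That letter coincides with the dye, so pairing cannot be separated from a dye effect, and none was used. The replicate block planned beforehand, by array title on Cy5 over Cy3, gave 96 loci (35 higher, 61 lower) against nitrogen flow at 1 min in place of 61 and moved no other count by over 1.5 times. A block on plasma-over-control ratios was tried after these counts were known, a change that alters the block for the 0 min arrays alone, since only there the dye orientation differs within a title letter; it gave 60 at 1 min against nitrogen flow and moved no count by over 1.5 times. Crossed letters in that block at 2 min gave 159 in place of 35 for the difference between 5 and 1 min against nitrogen flow.

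Among the named loci none changed direction, and a call was lost in 23 of 352 values, without those 2 settings. The 22 gene lists and their alternatives were not run, and contrasts across slides have no value with 1 slide. Signal over background limits the 2 min nitrogen flow array of replicate a, where 69.5% of Cy3 and 63.6% of Cy5 spots were well above background.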

Other observations

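The neighbour correlation, its random orders and the fits by channel were chosen after the data were seen; the tests of spot placement and intensity were written before their own results. Loci with consecutive numbers moved together. The effects of plasma against untreated cells at 1 min correlated between numerical neighbours with r = 0.47 over 5243 numbered loci, where 1000 random orders reached at most 0.043, and at 2 and 5 min with r = 0.48 and 0.19. Of the loci called at 1 min, 967 lay in runs of at least 5 consecutive loci that changed in the same direction, against a median of 128.5 in random orders, and the longest run held 18 loci that all fell. A run of 12 consecutive loci rose with a median log2 ratio of 5.02, and a run of 10 with a median of 3.42. The longest run in any random order held 14 loci. Against nitrogen flow, with fewer calls, the longest runs held 2 loci at 1 min, against 3 in random orders, and 6 at 2 and at 5 min, against 5, and neighbours correlated with r = 0.30, 0.29 and 0.24 at 1, 2 and 5 min. A run of 4 loci at 5 min had a median of -1.99. Neighbours also correlated at 0 min (r = 0.24), where no locus was called in limma and 162 passed an unadjusted p of 0.05.

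With 1 spot per locus, spots of neighbouring loci lay 0.98 times as far apart as random pairs in the median. This argues against neighbouring loci being generally placed close together on the array. The other spot of each locus was not examined, and a median cannot exclude a minority of close pairs. Removal of the trend with mean intensity left the neighbour correlation at 1 min at 0.47. The ratios had already been normalized on intensity by loess, so little trend was left to remove. This value therefore cannot weigh shared intensity as a cause. Joint transcription of neighbouring loci may underlie the runs; it is a hypothesis that was not tested, since positions and strands were not used here.

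Plasma at 1 min of exposure, fitted by channel on the slide of the nitrogen flow comparisons, gave effects against its own 0 min extracts that correlated across loci with those measured on the other slide (r = 0.95), as did 2 min (r = 0.93) and 5 min (r = 0.79). Nitrogen flow at 1 and 2 min against its own 0 min extracts correlated across loci with the plasma effects of the same slide at r = 0.96 and 0.94, and at 5 min at 0.74, channels of a common array included. Set against the indirect difference of nitrogen flow and untreated cells, which uses the same nitrogen flow extracts, they gave r = 0.95, 0.92 and 0.69 at 1, 2 and 5 min.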
